A study of Mus musculus with 7 samples.

How the data were processed

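RNA-seq libraries were made from mouse alveolar macrophages sorted, per the labels, as positive for CD11c, F4/80 and SiglecF. Poly(A) RNA was selected and turned into strand-specific libraries with NEBNext kits and read from one end on an Illumina NextSeq, per the labels' protocols. The submitters' processing notes name cutadapt 2.3, STAR 2.7.0d, RSEM 1.3.1 and the mm10 build, without their parameters. The authors deposited 1 table of TPM with 47643 genes by 7 libraries, given to 2 decimals. TPM divides each gene's reads by its length and scales every library to a sum of 1000000, so a few abundant genes that take more of the sum lower the values of all others, and sequencing depth cannot be recovered. Other upstream steps are not given in the sources used here, including the annotation and the strand setting of the quantification.

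Libraries were grouped from their titles as WT (n = 3), Lyz2cre (n = 3) and CD11ccre (n = 1). Gene IDs were matched to the GENCODE M21 annotation of GRCm38 (mm10) for symbols and coordinates, and 47224 of 47643 matched. The annotation release the authors used was not stated, and 14 of the 32 genes named from the rankings and targets overlap another gene in GENCODE M21, 8 of them on the same strand.

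The main test, fixed before the data were examined, was limma 3.58.1 in R 4.3.3 on log2(TPM + 1). Genes with a mean TPM of at least 1 were kept (11397), all 7 libraries entered 1 fit with a coefficient per genotype, and the moderated test used a mean-variance trend (4 residual and 3.35 prior degrees of freedom). Two-sided p-values were adjusted by the Benjamini-Hochberg method over all genes tested with a threshold of 0.05. The lone CD11ccre library adds no residual degree of freedom and is assumed to vary like the other groups. Mean TPM of the targets and Cre loci was also compared with exact two-sided permutation tests, which with 3 against 3 libraries cannot go below p = 0.1. Agreement of the Cre lines was set against 100 simulated sets of unchanged groups sharing the WT libraries.

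Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01, adjusted over lists. Of these, 16 lists described biology: alveolar macrophage identity, monocyte-derived and interstitial macrophage, profibrotic macrophage, alternative activation, inflammatory cytokines and chemokines, type I interferon response, NRF2 targets, HIF targets, cell cycle, unfolded protein and integrated stress response, cholesterol synthesis, PPAR and lipid handling, MHC class II presentation, extracellular matrix and adhesion, immediate-early and dissociation stress, and the core circadian clock. A further 4 held markers of alveolar type 2 cells, airway club and ciliated cells, fibroblasts and smooth muscle, and neutrophils. Another 7 marker lists (alveolar type 1 cells, endothelium, T and NK cells, B and plasma cells, eosinophils with basophils and mast cells, dendritic cells, erythroid cells and platelets) had fewer than 5 tested members and are given as levels. Sex genes and the targeted genes with the Cre loci served as checks. Apart from the checks, 20 of 532 listed genes stood on more than 1 list, so list calls are not independent. Counts "adjusted over the list alone" use the Benjamini-Hochberg method within a list.

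Genes were named by a rule fixed before the data were examined. It took the targets and Cre loci and, for each Cre line against WT, the 10 largest rises and the 10 largest falls among genes past the threshold. These had to have a mean TPM of at least 5 and no overlap between the compared libraries (for CD11ccre, a value outside the WT range), leaving out predicted models, pseudogenes and listed sex genes. The rule added up to 4 called members of each list with the smallest p, and up to 5 genes in each direction between the Cre lines. The values of 1 gene that the rule picked are not reported here. Genes named outside it are said to have been chosen after their values were seen.

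Further settings chosen before the data were examined were pseudocounts of 0.1 and 5, no filter on low values, a mean TPM of at least 5, median-of-ratios scaling, quantile normalization, limma without the trend or with robust fitting, the replicate number as a block, leaving out each WT and Lyz2cre library in turn, leaving out CD11ccre, camera with an estimated correlation, and fry. Refits with protein-coding genes only, without Ftl1, Fth1 and Chil3, and without these and Lyz2, each rescaled to 1000000, were chosen after seeing the data. The agreement of the Cre lines with separate WT controls was chosen then too. Leaving out a WT or Lyz2cre library, or adding the block, also lowers the residual degrees of freedom. A call can then end with little change in its effect.

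The gene test was tested on simulated data for 11397 genes with 200 changed. The changed genes were drawn only from the more abundant ones, with equal numbers up and down. Noise was independent between genes and no shift was common to all, so recovery of weaker genes was not measured. For Lyz2cre against WT the test recovered 67.5% of genes changed by 1 on the log2 scale and 98.5% of those changed by 2, with 4.93% and 7.94% false calls. For CD11ccre against WT it recovered 2.5% and 94%, with 0% and 5.53% false calls. With the NRF2 list shifted by 0.5 in a simulated Lyz2cre against WT comparison of 11397 genes, camera called that list and 0 of the others. Genes varied independently there, so the check does not measure false calls among lists of correlated genes. Exact tests and figures used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.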

Results

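Poly(A) RNA was sequenced from sorted mouse alveolar macrophages, the resident phagocytes of the lung airspaces, in 7 libraries. Of these, 3 were labelled wild type (WT). Another 3 came from animals whose floxed Siah1a and Siah2 were deleted by a Cre recombinase expressed from Lyz2, the lysozyme M gene (Lyz2cre). The remaining library came from the same floxed alleles with Cre driven by the promoter of CD11c, the product of Itgax (CD11ccre, n = 1). Siah1a and Siah2 encode RING-type E3 ubiquitin ligases, and the comparison asks how their loss alters alveolar macrophages. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these libraries. Values were TPM, length-scaled shares of each library that keep no record of depth, so the depth is unknown and no counting interval or floor is given. Log2 fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, while values given as N-fold are plain ratios of mean TPM and run higher for such genes.

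Between 10883 and 11518 genes reached 1 TPM per library. Mitochondrially encoded genes took 8.56% ± 0.902 (SD, n = 3) of the TPM in WT, 3.77% ± 0.996 (SD, n = 3) in Lyz2cre and 4.23% in CD11ccre. The ferritin chains Ftl1 and Fth1 and the chitinase-like Chil3 together took 5.06% ± 0.204 (SD, n = 3), 15.4% ± 0.939 (SD, n = 3) and 14.0% respectively. Across genes, Pearson's r of log2(TPM + 1) ran from 0.938 to 0.947 between WT libraries, 0.957 to 0.960 between Lyz2cre libraries and 0.919 to 0.935 between a WT and a Lyz2cre library. It ran from 0.952 to 0.960 between CD11ccre and Lyz2cre. No pair of libraries shared more than 1.79% of its values over the tested genes, so none looked like a copy of another. Xist, the X-inactivation RNA, was listed at 0 in every library, and the Y-linked Ddx3y averaged 47.9 TPM in WT, 31.3 TPM in Lyz2cre and 32.1 TPM in CD11ccre. The Y-linked Eif2s3y and Uty averaged 79.9 and 5.18 TPM in WT, 43.6 and 3.94 TPM in Lyz2cre and 54.4 and 4.36 TPM in CD11ccre. Kdm5d stood at 7.03, 4.81 and 6.15 TPM in WT, averaged 4.99 TPM in Lyz2cre and stood at 5.05 TPM in CD11ccre.

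Both targeted genes fell in both Cre lines. Siah1a (chromosome 8, 86724007 to 86745934, minus strand, mm10) stood at 16.59, 6.72 and 13.35 TPM in the WT libraries, was listed at 0, 0 and 0.05 in the Lyz2cre libraries and was listed at 0 in CD11ccre. Siah2 (chromosome 3, 58674938 to 58692400, minus strand) averaged 14.5 TPM ± 2.47 (SD, n = 3) in WT, 1.63 TPM ± 0.275 (SD, n = 3) in Lyz2cre and 1.21 TPM in CD11ccre. In limma, the log2 fold changes of Lyz2cre against WT were -3.62 ± 0.37 (SE, adjusted p = 0.00390) for Siah1a and -2.55 ± 0.22 (SE, adjusted p = 0.00228) for Siah2. The exact two-sided permutation test of the TPM means gave p = 0.1 for each, the smallest that 3 against 3 libraries allow. CD11ccre against WT gave -3.64 for Siah1a (adjusted p = 0.0195) and -2.80 for Siah2 (adjusted p = 0.00978), with the lone library assumed to vary like the others. The Siah1a call in CD11ccre ended without WT replicate 1 (adjusted p = 0.0588) and without WT replicate 3 (adjusted p = 0.0518). Across the 18 alternatives its adjusted p ran from 0.00452 to 0.0787. The paralogue Siah1b averaged 1.32 TPM ± 0.436 (SD, n = 3) in WT and 1.31 TPM ± 0.675 (SD, n = 3) in Lyz2cre (exact permutation p = 1), and Siah3 was listed at 0 in all libraries. Reads outside the deleted exons may remain in such a design, so the level of each target checks the labels only in part.

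The Cre loci differed in another way. Lyz2 (chromosome 10, 117277331 to 117282321), which encodes the lysozyme of macrophages, stood at 77.64, 72.56 and 86.25 TPM in WT, 46.62, 61.89 and 55.73 TPM in Lyz2cre and 50676 TPM in CD11ccre. Its low level was thus shared by the WT libraries, whose labels do not state whether they carry Cre. The Lyz2cre against WT difference in Lyz2 (log2 fold change -0.52) did not pass limma (adjusted p = 0.0633; exact permutation p = 0.1). Itgax averaged 362 TPM ± 31.6 (SD, n = 3) in WT, 429 TPM ± 6.59 (SD, n = 3) in Lyz2cre and 541 TPM in CD11ccre. Its adjusted p was 0.186 for Lyz2cre against WT, where the exact permutation p was 0.1, and 0.0746 for CD11ccre against WT. With median-of-ratios scaling the latter was 0.0221.

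**Figure D1:**
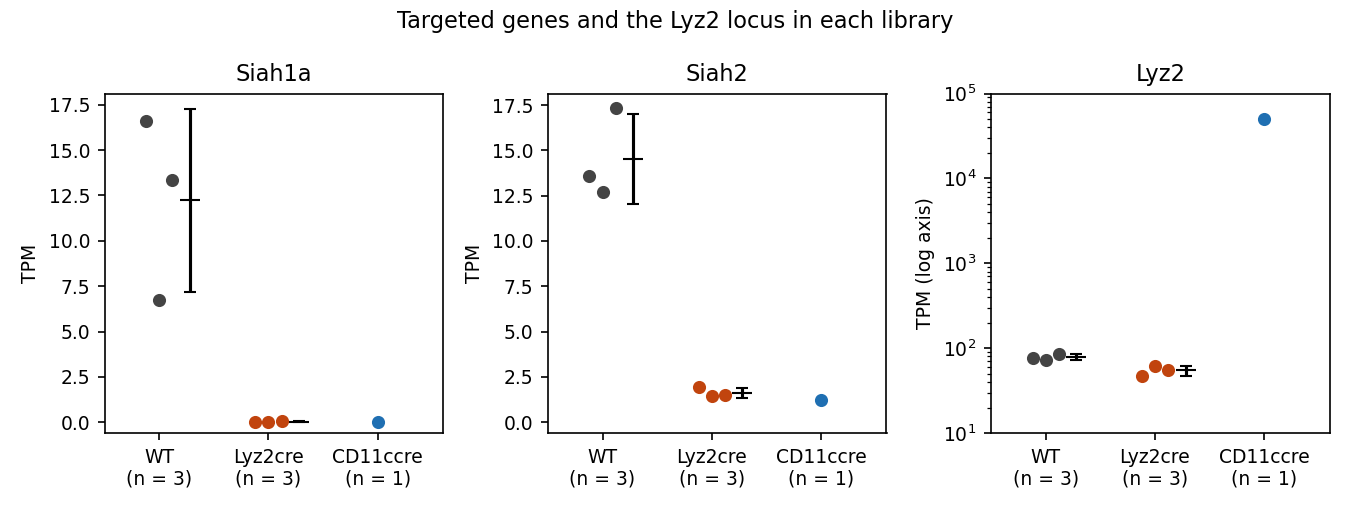
TPM of Siah1a, Siah2 and Lyz2 in each library (points), with the mean and SD of the 3 WT and the 3 Lyz2cre libraries beside them; the Lyz2 panel has a log axis. Both targets are lower in the Cre lines, and Lyz2 reaches 50676 TPM in the CD11ccre library only.

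In Lyz2cre against WT, the ferritin chains, Slc7a11 and Chil3 rose, while Gal and genes of class II antigen presentation fell. Slc7a11, the cystine and glutamate antiporter subunit, rose 11.3-fold, from 4.88 TPM ± 0.315 to 55.3 TPM ± 10.7 (SD, n = 3 each). Ftl1 rose 3.46-fold to 56034 TPM ± 4567 (SD, n = 3) and Chil3 rose 2.79-fold to 60484 TPM ± 7667 (SD, n = 3). The neuropeptide gene Gal fell 16.1-fold, from 156 TPM ± 12.6 (SD, n = 3) to 10.31, 10.74 and 7.96 TPM, and the class II invariant chain Cd74 fell 8.30-fold, from 244 TPM ± 104 to 29.4 TPM ± 7.53 (SD, n = 3 each).

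Under the naming rule the largest rises also took in Awat1, an acyl-CoA wax alcohol acyltransferase gene (chromosome X, 100572251 to 100578205), which rose 31.4-fold to 53.1 TPM ± 18.4 (SD, n = 3; log2 fold change 4.31, adjusted p = 0.00113). Ear6, an eosinophil-associated ribonuclease gene, rose 12.9-fold to 244 TPM ± 85.2 (SD, n = 3). Wfdc17 rose 10.8-fold to 437 TPM ± 156 (SD, n = 3). Mfge8, which bridges apoptotic cells to phagocytes, rose from 5.15, 9.97 and 5.85 TPM to 69.9 TPM ± 31.2 (SD, n = 3). Pla2g7, which hydrolyses platelet-activating factor, rose 10.6-fold, and Syngr1, a synaptogyrin, rose 10.3-fold. The complement component gene C4b rose from 0.820 TPM ± 1.13 to 10.6 TPM ± 2.41 (SD, n = 3 each; adjusted p = 0.0126), a call that ended without Lyz2cre replicate 3 (adjusted p = 0.0630). Erich6 (chromosome 3, 58616300 to 58637207, minus strand), near Siah2, stood at 0, 0.44 and 0 TPM in WT and 15.5, 8.67 and 9.48 TPM in Lyz2cre (log2 fold change 3.39, adjusted p = 0.00251). The 80 bp microRNA feature Mir1892 (chromosome 12, 54645933 to 54646012), inside Sptssa on the same strand, was listed at 0 in every WT library and at 63.85, 137.12 and 189.33 TPM in Lyz2cre. Its values are uncertain because the feature is short and overlaps another gene. Ear6 belongs to a family of near-identical copies, so the splitting of its reads is uncertain too.

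The largest falls, besides Siah1a, Gal and Cd74, were in Igflr1, Epcam, Erdr1, H2-Aa, Batf3, Cxcl14 and Wfdc10. Epcam, an epithelial cell adhesion molecule (chromosome 17, 87635979 to 87651129), fell 22.7-fold, from 35.9 TPM ± 9.74 to 1.58 TPM ± 0.789 (SD, n = 3 each; log2 fold change -3.86, adjusted p = 0.00207). Igflr1, a receptor for IGF-like ligands that overlaps another gene on its strand, fell 18.3-fold (adjusted p = 0.0159), a call that ended without WT replicate 1 (0.0597) or WT replicate 2 (0.0549). Erdr1, annotated on chromosome Y, fell 12.9-fold, from 271 TPM ± 34.1 (SD, n = 3) to 10.03, 31.27 and 21.73 TPM. The class II alpha chain H2-Aa fell 12.2-fold, the chemokine Cxcl14 fell 12.1-fold and Wfdc10 fell 6.26-fold. Batf3, a transcription factor of cross-presenting dendritic cells, fell 15.2-fold, from 14.9 TPM ± 9.48 to 0.980 TPM ± 0.841 (SD, n = 3 each; adjusted p = 0.0374). The Batf3 call ended with median-of-ratios scaling (0.0522) and without WT replicate 1 (0.109), WT replicate 2 (0.107), Lyz2cre replicate 1 (0.109), Lyz2cre replicate 2 (0.104) or Lyz2cre replicate 3 (0.0761).

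Among NRF2 targets, genes of the antioxidant response, 10 of 23 members rose, 0 fell and 13 were not called. Adjusted over the list alone, 14 rose and 1 fell. Besides Slc7a11 (adjusted p = 0.000780) and Ftl1 (adjusted p = 0.000780), Fth1 rose 2.92-fold to 37232 TPM ± 3090 (SD, n = 3) and the glutathione S-transferase Gstm1 rose 2.77-fold to 1320 TPM ± 166 (SD, n = 3). The list had a median log2 fold change of 0.89 and passed camera (adjusted p = 2.26e-19; adjusted p = 0.0817 with an estimated correlation). In the list of class II presentation, 8 of 9 members fell, 0 rose and 1 was not called, and adjusted over the list alone all 9 fell. H2-DMb1, part of the peptide-loading chaperone, fell 2.56-fold to 44.5 TPM ± 5.24 (SD, n = 3) and the class II beta chain H2-Eb1 fell 6.40-fold to 4.13 TPM ± 1.61 (SD, n = 3). The list median was -1.86 (camera adjusted p = 1.20e-08; adjusted p = 0.211 with an estimated correlation), and it was -1.69 with median-of-ratios scaling. Beside these class II genes, 11 of the 13 dendritic cell markers averaged below 1 TPM in WT, with a median over the markers of 0.227 TPM in WT and 0.160 TPM in Lyz2cre. Of the others, Batf3 fell and Ccl22 averaged 6.75 and 4.42 TPM (adjusted p = 0.249). Markers of B cells, which also express class II, were singled out after their values were seen. Igkc fell from 5.8, 4.59 and 15.12 TPM in WT to 1.18, 0 and 0.67 TPM in Lyz2cre (adjusted p = 0.0315) and stood at 0.44 TPM in CD11ccre, a call that ended when any 1 of the 6 libraries was left out (adjusted p 0.0548 to 0.0973). Ighm averaged 1.64 and 0.610 TPM (adjusted p = 0.307), and Cd22 averaged 34.1 and 44.0 TPM (adjusted p = 0.159).

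**Figure D2:**
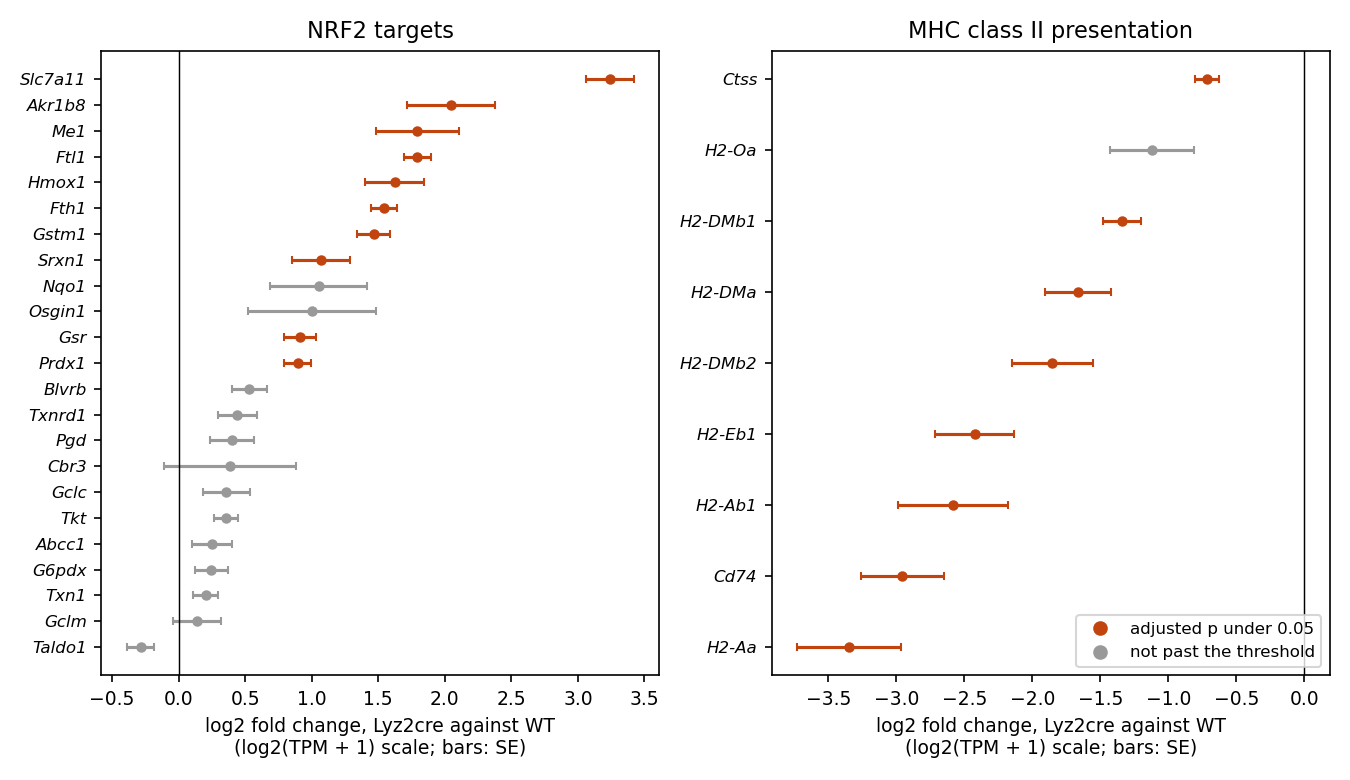
Log2 fold change of Lyz2cre against WT (n = 3 each, log2(TPM + 1) scale, bars are SE) for each tested NRF2 target and each class II presentation gene, coloured by whether the adjusted p was under 0.05. Of the NRF2 targets 10 of 23 rose, and of the class II genes 8 of 9 fell.

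Alveolar macrophage identity genes moved both ways, with 10 of 30 higher, 6 lower and 14 not called. Adjusted over the list alone, 11 rose and 9 fell. Besides Chil3, the collagen-degrading protease Ctsk rose 4.72-fold to 3678 TPM ± 338 (SD, n = 3) and the zinc transporter Slc39a2 rose 3.74-fold to 269 TPM ± 60.7 (SD, n = 3). The ribonuclease Ear1 fell 5.10-fold, from 2554 TPM ± 145 to 501 TPM ± 142 (SD, n = 3 each), with uncertain splitting of reads among its family. Siglecf, whose product was a sorting marker, averaged 231 TPM ± 23.3 in WT and 84.5 TPM ± 20.8 in Lyz2cre (SD, n = 3 each; adjusted p = 0.00746) and was singled out after its values were seen. The list median was 0.02 (camera adjusted p = 0.0277; adjusted p = 0.297 with an estimated correlation). The list call ended with median-of-ratios scaling (0.0650) and without WT replicate 1 (0.0546), Lyz2cre replicate 1 (0.0841) or Lyz2cre replicate 3 (0.0968).

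Of the profibrotic macrophage list 8 of 19 members rose, 2 fell and 9 were not called, with the same counts adjusted over the list alone. Gpnmb, a transmembrane glycoprotein of lysosomes, rose from 172 TPM ± 13.2 (SD, n = 3) to 616 TPM ± 50.7 (SD, n = 3), the lipid chaperone Fabp5 rose 2.65-fold to 1837 TPM ± 223 (SD, n = 3) and osteopontin (Spp1) rose 3.45-fold to 1939 TPM ± 234 (SD, n = 3). The matrix protein fibronectin (Fn1) fell 5.17-fold, from 191 TPM ± 13.7 to 36.9 TPM ± 13.7 (SD, n = 3 each), against the direction of the list. The list passed camera (median 0.66, adjusted p = 2.20e-05; adjusted p = 0.172 with an estimated correlation). In the extracellular matrix and adhesion list 3 of 16 rose, 1 fell and 12 were not called, and adjusted over the list alone 4 rose and 2 fell. The syndecan Sdc3 rose 1.85-fold and Sdc4 rose from 0.150 TPM ± 0.173 to 5.47 TPM ± 2.67 (SD, n = 3 each). The Sdc4 call ended without WT replicate 1 (0.0546), Lyz2cre replicate 2 (0.0757) or Lyz2cre replicate 3 (0.0836). This list also passed camera (median 0.05, adjusted p = 0.0243; adjusted p = 0.211 with an estimated correlation), but not without WT replicate 2 (0.0624), Lyz2cre replicate 2 (0.0508) or Lyz2cre replicate 3 (0.0522).

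Among monocyte-derived and interstitial macrophage genes, Cd14, the endotoxin co-receptor, rose 1.66-fold and the chemokine receptor Ccr2 fell 6.27-fold, with 8 of 10 not called and the same counts adjusted over the list alone. The Ccr2 call ended when any 1 of the 6 WT and Lyz2cre libraries was left out (adjusted p 0.0515 to 0.101) and with median-of-ratios scaling (0.0520). This list passed camera (median 0.23, adjusted p = 0.0243; adjusted p = 0.211 with an estimated correlation). Its call ended with median-of-ratios scaling (0.0560) and without WT replicate 1 (0.0601), WT replicate 2 (0.0716), Lyz2cre replicate 1 (0.0928), Lyz2cre replicate 2 (0.0685) or Lyz2cre replicate 3 (0.128). Of the inflammatory cytokines and chemokines 2 of 20 rose, 0 fell and 18 were not called, also adjusted over the list alone. Ccl2, a monocyte attractant, rose 7.41-fold to 5.66 TPM ± 1.18 (SD, n = 3) and Il1b rose 2.57-fold to 113 TPM ± 23.8 (SD, n = 3), the latter not passing without WT replicate 1 (0.0752), WT replicate 3 (0.0613), Lyz2cre replicate 1 (0.0789) or Lyz2cre replicate 2 (0.0790). The list call (median 0.05, adjusted p = 0.00946; adjusted p = 0.465 with an estimated correlation) ended without Lyz2cre replicate 1 (0.136).

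In the unfolded protein and integrated stress response list, Slc7a11, also on the NRF2 list, rose and Atf4 fell 1.49-fold. The other 25 of 27 members were not called, as when adjusted over the list alone. The list passed camera (median 0.08, adjusted p = 0.00946; adjusted p = 0.406 with an estimated correlation). The Atf4 call ended when any 1 of the 6 libraries was left out (adjusted p 0.0592 to 0.124) and with median-of-ratios scaling (0.123). In cholesterol synthesis Dhcr7, a reductase late in the pathway, rose 1.81-fold, while 0 of the 21 members fell and 20 were not called, also adjusted over the list alone. The Dhcr7 call held only without Lyz2cre replicate 1 among the leave-outs, with adjusted p 0.0802, 0.0644 and 0.0623 without WT replicates 1, 2 and 3 and 0.0908 and 0.1003 without Lyz2cre replicates 2 and 3. The cholesterol list passed camera (median 0.08, adjusted p = 0.0120; adjusted p = 0.399 with an estimated correlation), but not without WT replicate 1 (0.0594) or Lyz2cre replicate 3 (0.128).

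The other lists did not pass camera. In alternative activation 4 of 16 rose and 2 fell (5 and 4 adjusted over the list alone; adjusted p = 0.0913). With median-of-ratios scaling 5 of them rose and 0 fell. Besides Chil3, the chemokine Ccl17 rose 7.10-fold to 15.0 TPM ± 5.06, the transglutaminase Tgm2 rose 2.01-fold to 645 TPM ± 121 and Chil4, a near copy of Chil3, rose 3.67-fold to 6.38 TPM ± 0.890 (SD, n = 3 each). The Ccl17 call ended without Lyz2cre replicate 3 (0.0606). The Tgm2 call ended without WT replicates 2 and 3 (0.0667 and 0.0518) and without Lyz2cre replicates 1 and 2 (0.0702 and 0.0616), each left out singly. The Chil4 call ended without WT replicates 1 and 3 (0.0653 and 0.0580) and without Lyz2cre replicates 1, 2 and 3 (0.0898, 0.0664 and 0.104). In PPAR and lipid handling 3 of 27 rose and 3 fell (5 and 4 adjusted over the list alone; adjusted p = 0.125). Fatty acid-binding Fabp1 fell 3.55-fold and lipid droplet protein Cidec fell 2.46-fold, while the lysosomal lipase Lipa rose 1.96-fold and Fabp4 rose 1.69-fold. The Fabp4 call ended without WT replicate 2 (0.0513) or Lyz2cre replicate 3 (0.0630). Of 25 immediate-early and dissociation stress genes only Ier3 rose, 3.18-fold to 66.3 TPM ± 6.56 (SD, n = 3), also adjusted over the list alone (list adjusted p = 0.541). No member was called, over all genes or adjusted over the list alone, among 36 cell cycle genes (list adjusted p = 0.630), 24 HIF targets (0.594), 21 type I interferon response genes (0.289) or 12 core circadian clock genes (0.277). The median or mean was negative while the camera direction was higher in alternative activation, interferon response, HIF targets, PPAR and lipid handling, immediate-early genes, the circadian clock, club and ciliated markers and neutrophil markers, because camera compares a list with all other genes.

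Markers of other cell types were measured beside these groups. In neutrophil markers S100a8 rose 4.06-fold, from 24.9 TPM ± 8.70 to 101 TPM ± 23.5 (SD, n = 3 each), and Csf3r fell 2.53-fold, with 5 of 7 not called (2 higher and 3 lower adjusted over the list alone; list adjusted p = 0.289). The Csf3r call ended without WT replicates 1, 2 and 3 (0.112, 0.0747 and 0.0821), each left out singly, without Lyz2cre replicates 2 and 3 (0.0948 and 0.0989), and with median-of-ratios scaling (0.0568). In airway club and ciliated markers Tppp3 fell 3.25-fold, from 285 TPM ± 93.9 to 87.9 TPM ± 29.3 (SD, n = 3 each), with 6 of 7 not called (0 and 1 adjusted over the list alone; list adjusted p = 0.740). The Tppp3 call ended without WT replicates 1 and 2 (0.0692 and 0.0791) and without Lyz2cre replicates 2 and 3 (0.0664 and 0.0657). Of the same list, Scgb1a1 averaged 149 TPM in WT and 194 TPM in Lyz2cre, and Foxj1 0.637 and 0.547 TPM. RNA of airway markers was thus present in both groups, and the fall of Tppp3 alone gives no measure of ciliated cells. None of 6 alveolar type 2 cell markers (list adjusted p = 0.0526, but 0.0491 without WT replicate 3, 0.00585 with fry and 0.0441 with protein-coding genes only) or 8 fibroblast and smooth muscle markers (0.261) was called over all genes. Adjusted over the list alone, 2 type 2 cell markers rose and 1 fell, and no fibroblast marker was called. The 7 lists with under 5 tested members had low medians in WT and Lyz2cre. They were 0.210 and 0.253 TPM for alveolar type 1 cells, 0.0417 and 0.0517 TPM for endothelium, 0.240 and 0.0533 TPM for T and NK cells (Gzma 2.93 and 0.380 TPM, adjusted p = 0.0731) and 0.0300 and 0.0433 TPM for B and plasma cells. Erythroid and platelet markers had 0.447 and 0 TPM, and the median marker of eosinophils, basophils and mast cells was listed at 0 in both, although that list holds Ear6.

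Of 11397 genes tested, 771 passed limma at an adjusted p under 0.05 in Lyz2cre against WT, 247 higher and 524 lower. The 3 Lyz2cre and 3 WT libraries did not overlap in 3507 genes (30.8%), where chance gives 10% if no shift is common to all genes. That count was made on the deposited TPM only. The median log2 fold change of all genes was -0.16, and median-of-ratios scaling brought it to about 0. Scaled in that way, 550 genes passed, 339 higher and 211 lower, so that the share of higher calls went from 32.0% to 61.6%. All 247 genes called higher and 211 of the 524 called lower kept their calls, and 0 genes were called in opposite directions. The count fell to 384 without WT replicate 1, 333 without WT replicate 2, 354 without Lyz2cre replicate 1, 300 without Lyz2cre replicate 2 and 239 without Lyz2cre replicate 3. Of the 20 lists, 9 passed camera, 5 passed without Lyz2cre replicate 3, and 0 passed with an estimated correlation.

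**Figure D3:**
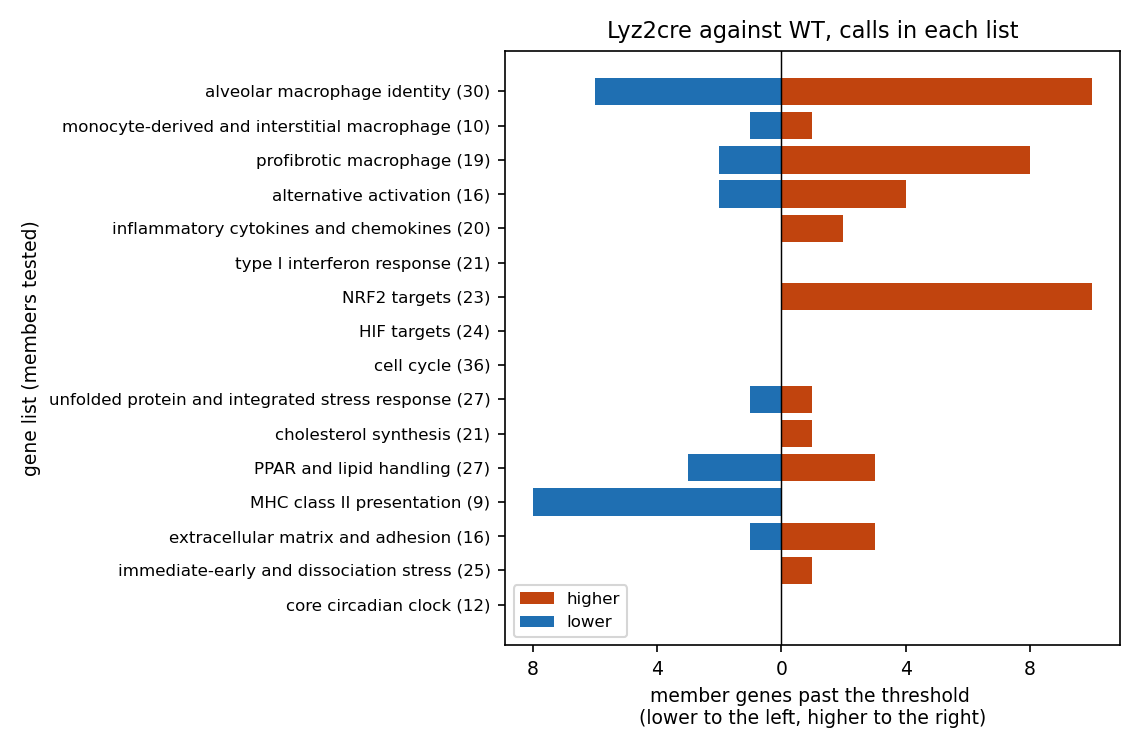
Number of member genes past an adjusted p of 0.05 in Lyz2cre against WT (n = 3 each) in each of the 16 biology lists, with the tested members in brackets; bars to the right count genes that were higher and bars to the left genes that were lower. NRF2 targets had 10 higher and 0 lower, and class II presentation 0 higher and 8 lower.

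CD11ccre against WT, resting on 1 CD11ccre library assumed to vary like the others, gave many of the same leading genes. Awat1 stood at 51.8 TPM against 1.69 TPM ± 0.743 (SD, n = 3) in WT (30.7-fold higher, adjusted p = 0.00756), Ear6 at 244 TPM (12.9-fold higher) and Wfdc17 at 468 TPM (11.5-fold higher). Ccl2 reached 16.5 TPM against 0.763 TPM ± 0.449 (SD, n = 3), 21.6-fold higher (adjusted p = 0.0106). Fn1 fell 16.4-fold to 11.6 TPM, Gal fell 14.8-fold to 10.5 TPM and Epcam fell 78.0-fold to 0.460 TPM.

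Lyz2 had the largest rise, at log2 fold change 9.31 (adjusted p = 1.95e-06). The ribonuclease Rnase2b rose 11.9-fold to 51.5 TPM, Syngr1 rose 12.4-fold to 25.1 TPM and Erich6 reached 9.08 TPM (log2 fold change 3.16, adjusted p = 0.0180). Their calls ended for Rnase2b without WT replicate 1 (0.0542) or WT replicate 2 (0.0510), for Syngr1 without WT replicate 1 (0.0543) and for Erich6 without WT replicate 1 (0.0526). The 80 bp microRNA features Mir1902 (chromosome 2, 104428861 to 104428940), inside Hipk3, and Mir1892 reached 46.6 and 37.7 TPM. Both were listed at 0 in every WT library, with the same uncertainty as above. Mir1902 was also listed at 0 in every Lyz2cre library, so no spread was measured for it. Among the falls, the calcium-binding S100a4 (chromosome 3, 90603771 to 90606045) was listed at 0 in CD11ccre and stood at 18.49, 23.15 and 9.16 TPM in WT (log2 fold change -4.07, adjusted p = 0.0113). Its value is uncertain, because Gm42674, which overlaps it on the same strand, was listed at 0 in WT and at 5.73 TPM in CD11ccre. Igflr1 fell from 68.4 TPM ± 21.3 (SD, n = 3) to 0.110 TPM, H2-Aa fell 10.8-fold, and Sap25, named for its association with the SIN3 corepressor, fell 15.3-fold. Tle6, a transcriptional corepressor, was listed at 0 against 9.13 TPM ± 1.14 (SD, n = 3), and Pagr1a fell 21.9-fold to 0.630 TPM with uncertain splitting of reads from overlapping genes. These last calls ended for Igflr1 without WT replicates 1, 2 and 3 (0.0746, 0.0728 and 0.0623) or Lyz2cre replicate 2 (0.0557), each left out singly. They ended for Tle6 without the same libraries (0.0867, 0.0888, 0.0671 and 0.0711) and with median-of-ratios scaling (0.0515). For H2-Aa they ended without WT replicates 1, 2 and 3 (0.0542, 0.0569 and 0.0604) or Lyz2cre replicates 2 and 3 (0.0612 and 0.0519). For Sap25 they ended without WT replicates 1, 2 and 3 (0.0637, 0.0782 and 0.0645), and for Pagr1a without WT replicate 1 (0.0717), WT replicate 2 (0.0824) or Lyz2cre replicate 1 (0.0667).

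NRF2 targets again had members that rose, 5 of 23, with 0 lower and 18 not called (10 higher and 1 lower adjusted over the list alone). Slc7a11 rose 7.02-fold, Ftl1 2.81-fold, and Fth1 2.53-fold, and Gstm1 reached 1285 TPM, each in the 1 CD11ccre library. The list median was 0.72 (camera adjusted p = 8.31e-13; adjusted p = 0.174 with an estimated correlation). In class II presentation 5 of 9 fell and 0 rose (8 lower adjusted over the list alone; median -1.94, camera adjusted p = 6.82e-06; adjusted p = 0.263 with an estimated correlation). With median-of-ratios scaling 3 class II genes were called lower. H2-DMb1 fell 2.66-fold, Cd74 7.98-fold and the invariant chain protease Ctss 1.78-fold. The H2-DMb1 call ended without WT replicate 1 (0.0588) and the Cd74 call without WT replicate 3 (0.0513). The Ctss call ended without WT replicates 1 and 2 (0.0639 and 0.0728), without Lyz2cre replicates 1 and 3 (0.0577 and 0.0516), each left out singly, and with median-of-ratios scaling (0.110).

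Alveolar macrophage identity had 6 of 30 higher, 4 lower and 20 not called (9 and 9 adjusted over the list alone). Ear1 fell 7.93-fold, Ear2 3.38-fold and Siglecf 4.29-fold to 53.9 TPM, while Chil3 rose 2.87-fold. The list median was 0.14 and its mean -0.01, with camera higher (adjusted p = 0.00405; adjusted p = 0.263 with an estimated correlation). Profibrotic genes had 3 of 19 higher and 1 lower (8 and 4 adjusted over the list alone; median 0.56, adjusted p = 0.000295; adjusted p = 0.263 with an estimated correlation). Gpnmb rose 3.43-fold, Fabp5 2.14-fold and Spp1 2.59-fold. The Fabp5 call ended without WT replicate 1 (0.0609) or WT replicate 2 (0.0567), and the Spp1 call when any 1 of the 6 WT and Lyz2cre libraries was left out (adjusted p 0.0517 to 0.0910). In extracellular matrix and adhesion 2 of 16 rose and 2 fell (4 and 3 adjusted over the list alone; median 0.01, adjusted p = 0.0431; adjusted p = 0.263 with an estimated correlation). Sdc4 reached 7.35 TPM and the urokinase receptor Plaur fell 1.60-fold. The Plaur call ended without any 1 of the 6 libraries (0.0641 to 0.0973) and with median-of-ratios scaling (0.305). The Sdc4 call ended without WT replicates 1, 2 and 3 (0.0939, 0.0851 and 0.0765) and without Lyz2cre replicates 2 and 3 (0.0824 and 0.0770). The matrix list did not pass without WT replicate 2 (0.0511), without Lyz2cre replicate 2 (0.0532) or with median-of-ratios scaling (0.0532).

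Slc7a11 was the only member called, over all genes or adjusted over the list alone, of the 27 unfolded protein and integrated stress response genes (median 0.11, adjusted p = 0.000170; adjusted p = 0.263 with an estimated correlation). No cholesterol synthesis gene of 21 was called in either way (median 0.15, adjusted p = 0.00243; adjusted p = 0.263 with an estimated correlation). Of 25 immediate-early and dissociation stress genes the small GTPase Rhob rose 2.40-fold, with 4 higher and 3 lower adjusted over the list alone (median 0.16, adjusted p = 0.00243; adjusted p = 0.372 with an estimated correlation). The Rhob call ended without WT replicates 1, 2 and 3 (0.0886, 0.103 and 0.0777) or Lyz2cre replicates 1 and 2 (0.0928 and 0.0612), each left out singly. No fibroblast and smooth muscle marker of 8 was called in either way (median 0.17, adjusted p = 0.0490; adjusted p = 0.263 with an estimated correlation). That list did not pass with median-of-ratios scaling (0.199) or without WT replicate 1 (0.0827), WT replicate 2 (0.0586), Lyz2cre replicate 1 (0.0776) or Lyz2cre replicate 3 (0.0528).

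In alternative activation Chil3 rose and the cytokine signalling suppressor Socs2 fell 2.21-fold, as when adjusted over the list alone (list adjusted p = 0.112). Among inflammatory genes Ccl2 rose and Tnfaip3, an inhibitor of NF-kappaB signalling, fell 2.85-fold, again with the same counts adjusted over the list alone (0.190). The Socs2 call ended without any 1 of the 6 libraries (0.0518 to 0.0791) and with median-of-ratios scaling (0.104). The Tnfaip3 call ended without WT replicates 2 and 3 (0.0739 and 0.0737), without Lyz2cre replicates 1, 2 and 3 (0.0741, 0.0753 and 0.0746) and with scaling (0.112). In PPAR and lipid handling Fabp4 rose 1.83-fold and Fabp1 fell 4.09-fold (3 and 4 adjusted over the list alone; 0.0995). The Fabp4 call ended without any 1 of the 6 libraries (0.0554 to 0.0907) and the Fabp1 call without WT replicate 2 (0.0632) or WT replicate 3 (0.0515). The lipid list passed with median-of-ratios scaling (0.0286) and without WT replicate 1 (0.0398), and cell cycle passed with scaling (0.0286). In neutrophil markers the collagenase Mmp8 rose 3.64-fold to 45.9 TPM and Csf3r fell 4.78-fold (2 and 2 adjusted over the list alone; 0.105). The Mmp8 call ended without WT replicate 1 (0.0639), WT replicate 2 (0.0586) or Lyz2cre replicate 2 (0.0563). The Csf3r call ended without WT replicates 1, 2 and 3 (0.0934, 0.0780 and 0.0747), without Lyz2cre replicates 1 and 2 (0.0601 and 0.0775) and with scaling (0.0627). No member was called in either way among cell cycle (list adjusted p = 0.0991), type I interferon (0.0634, and 0.0398 without WT replicate 1), HIF (0.527), circadian (0.490), monocyte-derived and interstitial (0.471), type 2 cell (0.0995) and club and ciliated genes (0.224). The median or mean was negative while camera was higher in the monocyte-derived, alternative activation, inflammatory, HIF, cell cycle, lipid, circadian, club and neutrophil lists.

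In all, 329 genes passed in CD11ccre against WT, 102 higher and 227 lower, and with median-of-ratios scaling 237 passed, 152 higher and 85 lower. With protein-coding genes only, a refit chosen after seeing the data, 131 were higher and 558 lower, and with no filter on low values 300 were higher and 193 lower. The median log2 fold change of all genes was -0.29 as deposited. The count fell to 95, 94 and 182 without WT replicates 1, 2 and 3 and to 157, 159 and 183 without Lyz2cre replicates 1, 2 and 3, again for a lone CD11ccre library assumed to vary like the others. Of the 20 lists 9 passed camera and 0 passed with an estimated correlation.

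The changes of both Cre lines against WT were compared across genes, which are not independent replicates and share the 3 WT libraries. Both lines called 89 genes higher and 150 lower, where independent lists would share 2.21 and 10.4, a figure that leaves out the shared controls, and 0 genes were called in opposite directions. With median-of-ratios scaling the shared calls were 128 higher and 56 lower, and with quantile normalization 101 higher and 54 lower. Slc7a11, Awat1, Ear6, Gal, Epcam and Cd74 were among the 239 genes. Of the 771 genes called in Lyz2cre, 759 had the same sign in CD11ccre. Pearson's r of the log2 fold changes was 0.677, against a mean of 0.354 and a highest value of 0.411 in 100 simulated sets of unchanged groups. With median-of-ratios scaling r was 0.664. The covariance was 0.294 against a simulated 0.0583, a difference of 0.236, and 79.2% of genes had the same sign against a simulated 61.5%. The simulated sets held no shift common to all genes, while the median log2 fold change was -0.16 in Lyz2cre and -0.29 in CD11ccre. Such a shared fall raises the share of same signs, also with separate controls, so that share does not measure agreement alone. Separate controls were chosen after seeing the data, as 2 WT libraries for Lyz2cre and the third for CD11ccre. With them r was 0.371 to 0.384, the covariance 0.197 to 0.207 and the share of same signs 66.7% to 68.5%. These comparisons share no library, so the simulated values above, made with shared controls, are no measure for them. Noise independent between libraries would give an r and a covariance near 0 there, but this was not simulated. Calls were not counted with separate controls, so part of their overlap may come from the shared controls. The overlap was 73, 68 and 130 genes without WT replicates 1, 2 and 3 and 109, 117 and 110 without Lyz2cre replicates 1, 2 and 3.

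**Figure D4:**
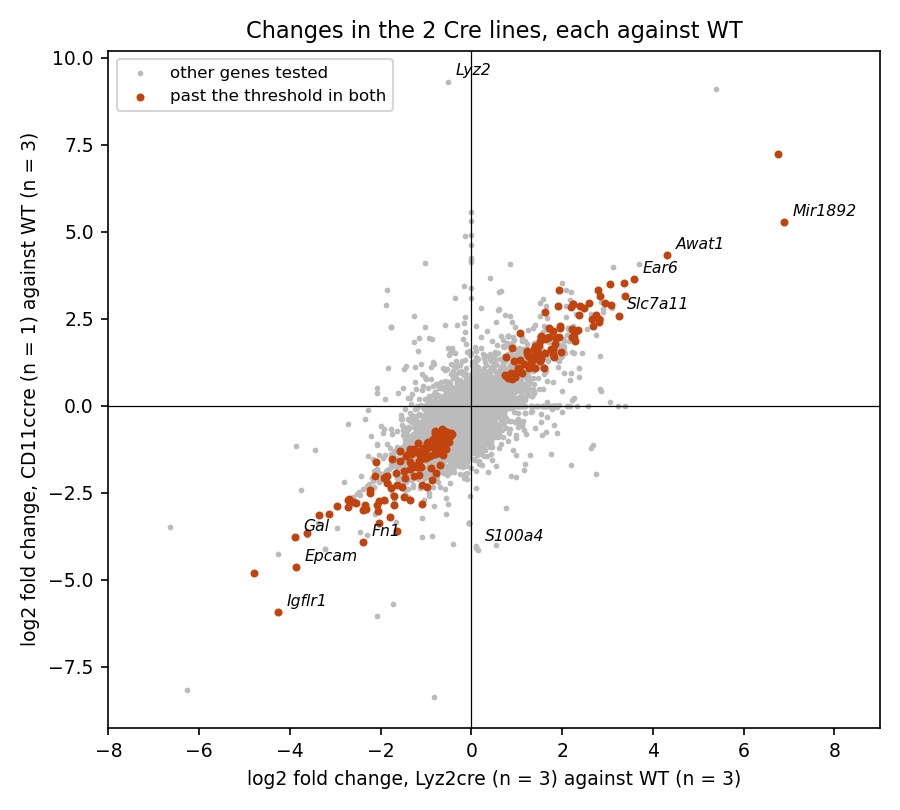
Log2 fold change of each tested gene in Lyz2cre (n = 3) and in CD11ccre (n = 1), each against the same 3 WT libraries, with the 239 genes past the threshold in both in colour. The coloured genes lie in the upper right and lower left, and Lyz2 and S100a4 lie apart.

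The direct comparison of CD11ccre with Lyz2cre asked which genes differed between the Cre lines, with 1 CD11ccre library assumed to vary like the others. Lyz2 rose 926-fold in CD11ccre, from 54.7 TPM ± 7.68 (SD, n = 3) to 50676 TPM (log2 fold change 9.84, adjusted p = 1.31e-06). S100a4 had 17.5 TPM ± 4.06 (SD, n = 3) in Lyz2cre and a listed 0 in CD11ccre (log2 fold change -4.18, adjusted p = 0.0391). The overlapping Gm42674 on its strand was listed at 0 in Lyz2cre and at 5.73 TPM in CD11ccre, so a shift of read assignment between them stays open. Mir1902 rose from 0 in every Lyz2cre library to 46.6 TPM. It was also listed at 0 in every WT library, so no spread was measured for it. Its call rested on the spread that the moderated test takes from other genes. In all, 13 of 11397 genes passed, 5 higher and 8 lower, and 695 had an unadjusted p under 0.05. With median-of-ratios scaling 17 passed, 9 higher and 8 lower. The count was 2 without WT replicate 2, 6 without WT replicate 3 and 2, 3 and 2 without Lyz2cre replicates 1, 2 and 3. The S100a4 call ended without WT replicates 1 and 2 (0.104 and 0.102) and without Lyz2cre replicates 1, 2 and 3 (0.177, 0.192 and 0.117). The Mir1902 call ended without WT replicate 2 (0.0571) and without Lyz2cre replicates 1, 2 and 3 (0.118, 0.114 and 0.105). Cell cycle genes (median 0.12, camera adjusted p = 0.00424; adjusted p = 0.702 with an estimated correlation) and immediate-early genes (median 0.36, camera adjusted p = 0.00424; adjusted p = 0.711 with an estimated correlation) were higher in CD11ccre as lists. No single member of them was called over all genes, and adjusted over the list alone 0 cell cycle genes and 2 immediate-early genes rose. The other 18 lists did not pass, except that the unfolded protein and integrated stress response list did with median-of-ratios scaling (0.0288), and 0 of their members were called over all genes. Their median or mean was negative while camera was higher for identity, interferon, HIF, cholesterol, lipid, class II, matrix, type 2 cell and neutrophil lists. Adjusted over the list alone, 1 matrix gene rose and 2 fell, and 1 monocyte-derived macrophage gene and 1 profibrotic gene fell.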

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

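The tests of explanations in this part were chosen after the results were seen. The direct test between the Cre lines called 13 genes, with 1 CD11ccre library on one side, so they may be properties of that library, and leaving out any 1 Lyz2cre library left 2 or 3 calls. The log2 fold changes of CD11ccre against Lyz2cre were 9.84 for Lyz2, 5.57 for Mir1902 and -4.18 for S100a4. Gm42674, which overlaps S100a4 on its strand, was listed at 0 in WT and Lyz2cre and at 5.73 TPM in CD11ccre, so whether S100a4 reads were lost or assigned to it stays open. The other 10 were singled out after their values were seen. The short features Gm28019, Snord16a and Gm22422 were listed at 0 in all WT and Lyz2cre libraries and at 38.4, 29.1 and 23.5 TPM in CD11ccre. For these features and Mir1902 no spread was measured, so their calls rested on the spread that the moderated test takes from other genes. The near-identical pseudogenes Rpl35a-ps2, Rpl35a-ps3, Rpl35a-ps4, Rpl35a-ps6 and Gm10243 shared the same values in each library, 9.09 TPM ± 1.53 (SD, n = 3) in Lyz2cre and a listed 0 in CD11ccre. Gm7206, another pseudogene, stood at 188 TPM ± 34.7 (SD, n = 3) in Lyz2cre and was listed at 0 in CD11ccre, and Gm43305 averaged 32.4 TPM ± 1.21 (SD, n = 3) and stood at 8.08 TPM. In CD11ccre 8 genes, S100a4 among them, were listed at 0 while every other library had at least 5 TPM, and in WT replicate 3 there were 14 such genes.

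Lyz2 stood far lower in the WT and Lyz2cre libraries than in CD11ccre. Reads lost to its near copy Lyz1 are argued against, since Lyz1 and Lyz2 summed were still 367-fold higher in CD11ccre than in WT, and so is a lower share of alveolar macrophages in WT, since the identity list had a median log2 fold change of only 0.14. Mean Lyz2 in WT was 1.44 times that in Lyz2cre, a level that WT mice carrying the Lyz2 knock-in allele without floxed Siah genes could give. Both copies of Lyz2 would have to carry it, because 1 intact copy would be unlikely to leave WT 643-fold below CD11ccre. In that case CD11ccre and WT would differ at Lyz2 as well as at the Siah genes. The labels do not give the Cre status of the WT animals, so the knock-in allele in WT stays a candidate explanation. In Lyz2cre, where Cre is expressed from Lyz2, that allele could lower Lyz2 too. With 1 CD11ccre library a difference between the Cre lines and a property of that library still cannot be separated.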

How the results depend on the processing

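The refits with protein-coding genes only, without Ftl1, Fth1 and Chil3, and without these and Lyz2 were tests chosen after the results were seen, and the other settings were chosen before. In Lyz2cre against WT the count of 771 genes became 342 with no filter on low values and 436 in eBayes without trend. In CD11ccre against WT the 329 became 201 with quantile normalization, 122 in eBayes without trend, 689 with protein-coding genes only, 216 without Ftl1, Fth1 and Chil3, and 205 without these and Lyz2. CD11ccre against Lyz2cre went from 13 to 210 with no filter on low values and to 2 with protein-coding genes only, and the agreement of the Cre lines from 239 to 155 with quantile normalization. Lists past the threshold went from 9 to 0 with an estimated correlation in each Cre line, and with fry to 5 in Lyz2cre and 2 in CD11ccre. Chil3 reversed in Lyz2cre against WT with quantile normalization, at -0.0734 (adjusted p = 0.740), a setting that gives genes of the same rank the same value and so leaves little room for the most abundant genes to differ. The cause of the other moves was not tested.

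Leaving out 1 library gave 239 to 514 genes in Lyz2cre against WT, 94 to 183 in CD11ccre against WT and 2 to 11 in CD11ccre against Lyz2cre. The agreement ran from 68 to 130 genes and lists in Lyz2cre from 5 to 10. Siah1a in CD11ccre ran from -3.99 to -3.40. Each such fit has fewer residual degrees of freedom, which raises p-values without any change in effect. Without Lyz2cre replicate 1, 2 or 3, Siah1a in CD11ccre against WT stayed at its main value of -3.64, while its adjusted p rose. An ended call thus does not by itself mark dependence on the library left out. How much of each move came from lost degrees of freedom was not tested.

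With the replicate block the counts were 390, 21 and 3 genes and the agreement 16. Siah1a in CD11ccre was -3.88 (adjusted p = 0.0787) and Siah2 -2.84 (adjusted p = 0.0740), nearly the main values. The block also takes residual degrees of freedom from the fit. Same-numbered WT and Lyz2cre libraries had correlations of -0.015, 0.043 and 0.066 after removing group means, so the numbers gave no pairing to use. The TPM hide depth, so how far low counts limit weak genes could not be measured.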

Other observations

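The tests and the 9 gene families in this part were chosen after the results were seen, except that the expected direction for the refit of CD11ccre without 4 genes was written before it was run, with the refit without 3 genes already known to give 46.8% higher. Families looked at were mitochondrially encoded mRNAs, V-ATPase subunits, cathepsins, eosinophil-associated ribonucleases, cytosolic and mitochondrial ribosomal proteins, metallothioneins, glutathione S-transferases and RNA polymerase II subunits. In Lyz2cre against WT 10 of 13 mitochondrially encoded mRNAs fell and 0 rose, also with median-of-ratios scaling. Among them mt-Cytb fell 2.53-fold to 3004 TPM ± 725 (SD, n = 3). In CD11ccre 0 of 13 were called, with a median log2 fold change of -1.10. Of 11 cathepsins, lysosomal proteases, 4 rose (Ctsd, Ctsk, Ctsl and Ctsb), 1 fell (Ctss) and 6 were not called, and Ctsd rose 3.38-fold to 16347 TPM ± 1654 (SD, n = 3). Of ribonucleases of the Ear family 2 of 5 rose and 2 fell. Of 83 cytosolic ribosomal protein genes 12 fell and of 74 mitochondrial ones 7 fell, and 2 of each still fell with median-of-ratios scaling. RNA polymerase II subunits had 4 of 13 lower, and 0 with scaling. V-ATPase subunits had 1 of 19 higher, Atp6v0c, and 2 with scaling. Glutathione S-transferases had 1 of 11 higher (Gstm1) and 1 lower (Gstp1, adjusted p = 0.0434), and 0 lower with scaling. Of 2 metallothioneins 0 were called, and 1 was higher with scaling.

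Single genes picked from the results added to this picture in Lyz2cre. The growth factor Igf1 rose 4.72-fold to 150 TPM ± 33.9 (SD, n = 3), the scavenger receptor Msr1 7.32-fold, the metal transporter Slc11a1 7.93-fold, the chemokine Ccl6 2.79-fold, the prostacyclin receptor Ptgir 7.80-fold and the saposin precursor Psap 2.33-fold. The Fc receptors Fcgr2b and Fcgr1 fell 2.88-fold and 2.41-fold, the lectin receptors Colec12 and Clec12a 5.53-fold and 4.03-fold, properdin (Cfp) 2.84-fold and the actin regulator Coro1a 2.94-fold. Each kept its direction and call with median-of-ratios scaling. Lyz1, the near copy of Lyz2, fell 5.02-fold to 11.8 TPM ± 3.13 (SD, n = 3), with uncertain splitting of reads between the copies.

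More genes were lower than higher in each Cre line against WT as first tested. Without Ftl1, Fth1 and Chil3, 59.6% of Lyz2cre calls were higher, and in CD11ccre, without these genes and Lyz2, 56.6% were, so the share these genes took was large enough to move the balance. Such a refit multiplies all other genes of a library by 1 factor, and median-of-ratios scaling (61.6% higher in Lyz2cre) centres the median of all genes, so either moves the balance whatever the cause, which stays open. With protein-coding genes only the share was 24.2% in Lyz2cre and 19.0% in CD11ccre, and with no filter on low values, and no rescaling, it was 60.9% in CD11ccre (300 higher and 193 lower) and 40.1% in Lyz2cre (137 higher and 205 lower). The share of higher calls thus depended on scaling in each Cre line, and on filtering in CD11ccre, so neither split gives a count of genes lowered by loss of Siah1a and Siah2.

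The fall of class II presentation genes had a scaled median of -1.69, which argues against a share effect as its source. The median of the dendritic cell markers was 0.227 TPM in WT and 0.160 TPM in Lyz2cre, which gives no support to dendritic cells as a source, and a sort on F4/80 and SiglecF would remove most of them, but markers this low cannot exclude a few such cells. Batf3 fell from 14.9 to 0.980 TPM, while Clec9a averaged 0.593 and 1.80 TPM and 11 of the 13 markers averaged below 1 TPM in WT. B cells were not tested as a source and stay open, given the fall of Igkc. As a hypothesis, loss of the ligases lowers class II expression within the macrophages, which protein measured per cell would test.

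Erich6 rose beside Siah2, 37730 bp away, and ranked 1 of 3 tested genes downstream on that strand. Erich6 was looked at because of its large rise, so that rank was largely fixed beforehand and decides nothing. It was the only 1 called of 16 tested genes within 1 Mb of Siah1a or Siah2 (6.25%), against 6.75% elsewhere (Fisher's exact p = 1). Transcription running past Siah2 and a separate change cannot be told apart, because genes between them were listed at 0 in most libraries. Splits of the 6 WT and Lyz2cre libraries number 10, too few for a share under 0.05. The real one gave 771 genes and 9 lists, the highest of the others 3 genes and 7 lists, so 1 of 10 reached each real count. The other splits mix WT and Lyz2cre libraries on each side, so a difference between the groups widens their spread and lowers their gene counts. Their low gene counts are thus no measure of what unchanged groups would give.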
